A study of Oryza sativa Japonica Group with 10 samples.

How the data were processed

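Roots of 2-week-old rice seedlings (Oryza sativa, japonica) were measured on 10 arrays of 1 colour: 3 of the cultivar Nipponbare, 3 of the cultivar Jamaica and 4 of their F1 hybrid. Per the labels, the replicates are biological and came from different plant individuals, and the hybrid roots are called abnormal. Per the labels' protocols, seedlings germinated under sterile conditions and grew on MS medium, a standard plant culture medium, at 25 °C in constant light, and total RNA was purified with a plant RNeasy kit. Per the labels' protocols, 100 ng of it was copied into cRNA carrying the dye Cy3. Groups and replicate numbers were taken from the sample titles, and every array was used.

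Per the file headers, the authors' scanner files were written by Agilent Feature Extraction 9.5.3.1, and each holds 45151 spots, of which 43224 carry rice probes and 1927 are controls. The deposited files give each spot's raw, background, background-subtracted and processed intensity on a linear scale, together with flags for control spots, saturation, spot outliers and spots well above background. The authors' deposited series table is also an intensity: in each of its columns 99.98% to 100.0% of the entries lay within 1% of the background-subtracted intensity divided by 1 constant per array. That comparison used entries with a signal of at least 200. Column medians were 0.99999994 to 1, the lowest entry was 0.01, and the 42477 entries were all matched by probe name. How that table was made is not given in the sources used here.

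In the main setting, the processed intensity was averaged over the spots of a probe without outlier flags, divided by the array's 75th percentile, raised to a floor of 0.00912 of that percentile (the highest, over arrays, of the lowest signal well above background) and taken as log2. Control spots were left out, with 510 spots named as controls but not marked so. A probe counted as well above background on an array where at least 0.5 of its spots were, and a probe was tested when it was well above background on every array of at least 1 group. This left 37299 of 42426 probes, for 25915 genes, and 26 probe values were missing because of outlier flags. Gene names are locus names and product names as the array files give them, which date from the array's design. Of the probes, 41908 carried a locus name (29690 loci), and 0 of these loci and 0 probe accessions were found in the reference gene table, so the names were not updated. The array files give no coordinates that were used, and no genome was used here.

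Differences were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 over the 3 groups at once, with no block, and p-values were adjusted by Benjamini-Hochberg over all probes, with calls under 0.05. The fit had 7 residual degrees of freedom, a prior of 2.07 and a median residual SD of 0.168. An F1 probe was called outside both parents when it was called in the same direction against Nipponbare and against Jamaica. The F1 was also compared with the mean of the parents' log2 values. Tables were read and drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The probe with the highest mean over all arrays stood for a gene in the lists, and different probes of a named gene were compared.

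The comparisons, their tests, the rule for named genes, the lists and the alternatives were fixed before the data were examined, except where a choice is said to be later. The 30 lists were built from product names and locus names: pathogenesis-related (PR) proteins, diterpenoid phytoalexin loci, phenylpropanoid and lignin enzymes, the tryptophan and serotonin branch, WRKY factors, class III peroxidases, glutathione S-transferases, NB-LRR receptors, wall-associated kinases, a list of respiratory burst oxidases, metacaspases and vacuolar processing enzymes, heat shock proteins and chaperones, jasmonate synthesis and JAZ, auxin response and transport, ethylene synthesis and ERF, cell wall expansion and cellulose, cell cycle and DNA replication, histones, ribosomal proteins, aquaporins, nitrogen uptake, phosphate response, iron uptake, sucrose cleavage with trehalose and starch, anaerobic metabolism, and markers of shoot photosynthesis, seed storage and late embryogenesis, vessel and sclerenchyma walls, endodermis and exodermis, root hair and epidermis, and root cap and meristem. The heat shock and photosynthesis lists share 5 genes, the cell wall and vessel lists 4, and the cell wall and root hair lists 1. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists, with an estimated correlation and fry (which tests whether the genes of a list move on balance one way) as alternatives. The share of a list outside both parents was compared with that of the remaining genes by Fisher's exact test, two-sided, adjusted over the lists and both directions. Like the later Fisher's exact tests, it counts genes as independent, although genes of a list can move together on the same arrays. Its p-values can therefore be too small, and these shares were not tested by splits of the arrays. Counts adjusted over the list alone use the same fit with the adjustment restricted to the list's genes.

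Named genes were the 12 above and the 12 below both parents with the largest smaller-of-both differences, among genes with a product name and well above background on all arrays (1204 above, 1221 below). Up to 4 genes per direction known only by a bound were added (from 7 above and 20 below), the 8 highest and 8 lowest in Jamaica against Nipponbare, and up to 4 members per list. The text prints up to 4 members for lists that were called and fewer for others; members named because a count was 5 or fewer, or for their product name, were chosen after their values were seen. A group with no array well above background has only a bound for that probe. The bound sets the bright group's mean normalised log2 value against the dim group's mean of, per array, the higher of the lowest signal well above background and the probe's own value, and is given as at least N-fold.

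The calling was tested on simulated data with 200 changed probes among 37299. For F1 outside both parents, 10.0% of changes of log2 0.5, 67.0% of changes of log2 1 and 92.5% of changes of log2 2 were recovered. For F1 against Nipponbare the shares were 13.5%, 69.5% and 93.5%, for F1 against Jamaica 12.5%, 72.0% and 94.0%, and for F1 against the parental mean 28.0%, 79.0% and 95.5%, with at most 14 false calls. The pairwise comparisons of the real data called 13453 to 16390 probes, so the adjustment admits larger p-values there. These shares and false calls therefore do not carry over to the real counts. In a simulation over 25915 genes with 24 lists of 100 genes, camera recovered 4 of 4 lists shifted by log2 0.3. No list without a shift was called. The simulated genes varied independently, whereas real lists had correlated genes (estimated correlation 0.615 for ribosomal proteins). The simulation therefore does not show how many false lists to expect here. The number of arrays limits the precision. Slide 1, 2 and 3 each held 1 array of every group (slide 3 a further F1 array) and each was 1 scan, so slide and scan are 1 batch, tested as a block and within each slide. On every slide Nipponbare lay at position 1, Jamaica at 2 and the F1 at 3, with the further F1 array at 4. No position held arrays of different groups, so position on the slide and group cannot be told apart. After removing group means, Jamaica and Nipponbare arrays of the same number correlated at r = 0.204, 0.302 and 0.549, all above 0.1, so by the rule used here the number pairs these samples. The labels name no shared batch, and Jamaica replicate 2 also correlated with Nipponbare replicate 1, of another number, at r = 0.305. Same-numbered parental arrays share a slide, but F1 and parental arrays of 1 slide correlated at r from -0.41 to 0.274, so where the pairing comes from is not known.

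Alternatives were quantile normalization, normexp background correction (offset 50) of the mean signal, no filter on dim probes, a filter asking for all 10 arrays, the deposited table, only the groups compared, eBayes with trend and robust, the replicate number or the slide as a block, a further 2-fold threshold, leaving out each array, fry, an estimated correlation and all probes of a gene. Medians of lists under another scaling, where the text gives them, keep the probes of the main setting, whereas the alternatives choose the probe of a gene anew. Added after seeing the data were the parental mean on the linear scale, a call of a list against each parent, and F1 arrays split into 2 sets of 2.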

Results

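The 10 arrays compared roots of the rice cultivars Nipponbare and Jamaica (3 arrays each) with the abnormal roots of their F1 hybrid (4 arrays), a cross that shows hybrid weakness, the poor growth of a hybrid between normal parents. The 75th percentile of the processed signal was 2289 to 3245 per array, 83.7% to 89.2% of the spots lay well above background, and 0 spots were saturated. Arrays of a group correlated at r of at least 0.985 across probes and arrays of different groups at most 0.966, and no pair of arrays was identical. The main axis of variation held 52.4% of the variance and the next 33.9%. Differences are log2 values. Where a pair of values follows a gene, it gives F1 minus Nipponbare and then F1 minus Jamaica (n = 4 F1 arrays against 3 of each parent).

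The question of this comparison is which transcripts of the F1 roots lie above or below both normal parents. Chitinase genes were among the largest increases: those at Os05g0399400 (log2 5.41 ± 0.44 and 2.83 ± 0.44), Os03g0132900 (log2 3.12 ± 0.20 and 4.66 ± 0.20) and Os11g0701800 (log2 2.76 ± 0.22 and 3.27 ± 0.22) rose above both parents, and chitinases cleave chitin. On the linear scale these were 42.4-fold, 8.71-fold and 6.79-fold the Nipponbare level. A ubiquitin-conjugating enzyme at Os02g0721100 (log2 3.66 ± 0.29 and 3.63 ± 0.29), a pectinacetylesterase at Os01g0892500 (log2 3.49 ± 0.19 and 3.82 ± 0.19) and an ATP-dependent RNA helicase-like gene at Os06g0602400 (log2 4.60 ± 0.16 and 3.41 ± 0.16) rose as well. A chalcone synthase, the entry enzyme of flavonoid synthesis, at Os07g0526400 rose (log2 3.71 ± 0.16 and 3.05 ± 0.16), as did a glutathione S-transferase at Os01g0370900 (log2 3.12 ± 0.22 and 3.91 ± 0.22). Further genes above both parents were a NAM-domain gene at Os10g0571600 (log2 3.02 and 2.99), a glycine-rich cell wall structural protein at Os10g0450900 (log2 2.93 and 3.50), an eggshell-family gene at Os10g0452300 (log2 2.85 and 3.43) and a C6HC-type zinc-finger gene at Os09g0283600 (log2 2.82 and 4.18). For all 12 genes every F1 array lay above every parental array, and adjusted p-values from limma were 1.5e-07 to 8.0e-04. Another probe of Os10g0450900 gave log2 2.03 and 3.12, and its remaining probes had all 3 Jamaica values at the floor. At Os02g0721100, 2 of the 3 Jamaica values lay at the floor. Normexp background correction, which compresses dim signals by its offset, ended the call against Nipponbare of Os02g0721100 (0.0957), Os07g0526400 (0.0504) and Os10g0452300 (0.0583) (adjusted p in parentheses).

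The small subunit of Rubisco at Os12g0291100 (log2 -3.25 ± 0.30 and -3.16 ± 0.30) and sedoheptulose bisphosphatase at Os04g0234600 (log2 -3.57 ± 0.30 and -3.36 ± 0.30) fell below both parents. Fructose bisphosphatase at Os03g0267300 (log2 -3.73 ± 0.34 and -3.31 ± 0.34) and a gene named GADPH at Os04g0459500 (log2 -3.45 ± 0.31 and -3.13 ± 0.31) fell as well, and the first 3 of these 4 are enzymes of the Calvin cycle. So did photosystem I subunit III at Os03g0778100 (log2 -3.33 ± 0.26 and -3.28 ± 0.26) and leaf ferredoxin-NADP reductase at Os06g0107700 (log2 -3.37 ± 0.28 and -3.26 ± 0.28). Further genes below were ferredoxin I at Os08g0104600 (log2 -3.50 and -3.36), a ferredoxin-domain gene at Os07g0489800 (log2 -3.37 and -3.83) and a thylakoid lumenal protein at Os12g0564400 (log2 -3.12 and -3.68). Hydroxypyruvate reductase of photorespiration at Os02g0101500 fell (log2 -3.73 and -3.44). The largest decrease among the named genes was that of Os03g0103200 (log2 -4.67 ± 0.24 and -5.29 ± 0.24), named as induced by physical impedance, beside its neighbour in locus number Os03g0103100 with the same product name (log2 -3.29 and -3.75). For all 12 genes every F1 array lay below every parental array, with limma adjusted p-values of 2.2e-07 to 4.8e-05. Other probes fell less at some of these loci: log2 -1.81 and -1.44 at Os03g0267300, and -1.87 and -1.63 at Os04g0459500. Another probe of Os02g0101500 gave log2 -2.41 and -1.21, with all 4 F1 values at the floor.

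Some genes were known only by a bound in the dim groups. A leucine-rich repeat gene at Os10g0120300 was at least 7.48-fold higher in the F1 than in either parent, where no array was well above background. The same held for embryo-specific protein ATS1 at Os04g0510900 (at least 4.21-fold), a protein kinase at Os06g0165500 (at least 4.01-fold) and a transferase at Os10g0379100 (at least 3.03-fold). In the other direction, no F1 array was well above background for a TPR-like gene at Os01g0358300 (at least 5.04-fold lower than either parent), though another probe of this locus was not outside both, with all 4 F1 and 3 Nipponbare values at the floor. The others were a metallophosphoesterase gene at Os10g0394100 (at least 4.50-fold), a galactose mutarotase-like gene at Os03g0748300 (at least 3.91-fold) and a SpoU methyltransferase gene at Os03g0685100 (at least 3.77-fold). Adjusted p-values from limma were 4.9e-09 to 0.0210. Every value of the dim groups lay at the floor, where values do not vary. The floor thus takes spread out of the fit, and these p-values can be too small. Under normexp the calls were lost against Nipponbare of Os10g0120300 (0.304), Os04g0510900 (0.623), Os06g0165500 (0.755) and Os10g0379100 (0.725) and against Jamaica of Os04g0510900 (0.167), Os06g0165500 (0.171), Os10g0379100 (0.255) and Os03g0685100 (0.0564) (adjusted p in parentheses). The call of Os10g0379100 was also lost against Nipponbare without Nipponbare replicate 1 or 2 (adjusted p 0.0562 to 0.0575) and against Jamaica without F1 replicate 1, 3 or 4 or Jamaica replicate 1, 2 or 3 (adjusted p 0.0524 to 0.0616).

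In all, 2632 probes lay above both parents and 3152 below (limma, adjusted over 37299 probes), together 5784 or 15.5%. At 2-fold or more they were 509 above and 1448 below. They stood for 1902 genes above and 2040 below. With slide as a block 5348 were called. Over all probes tested, F1 minus the parental mean within slide 1, 2 or 3 correlated with that of the other slides at r = 0.937, 0.808 and 0.772. Because the same F1 arrays enter both differences, these share chance values. Over all probes the differences correlated at r = 0.277 with a covariance of 0.198. In 20 simulations with no effect these were r = 0.430, a covariance of 0.0169 and 0 probes outside both. No simulated probe differed between any groups, so the adjustment alone leaves about 0 calls there. That count does not show how often a probe differing from 1 parent is falsely called outside both. Independent call lists would have shared 1566 probes above and 1322 below. With different F1 arrays against each parent (6 splits into 2 sets of 2, added after seeing the data) 1646 to 1938 lay above and 2521 to 2747 below, with r from 0.195 to 0.302. Of the 16390 probes that differed between the parents, 13.7% lay outside both (945 above, 1298 below). Of the 20909 probes not called between the parents 16.9% did (1687 above, 1854 below). Normexp moved the median of all probes from 0.02 to -0.17 in F1 minus Nipponbare, and called 3092 outside both, of which 32.7% were above, against 45.5% in the main setting.

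**Figure D1:**
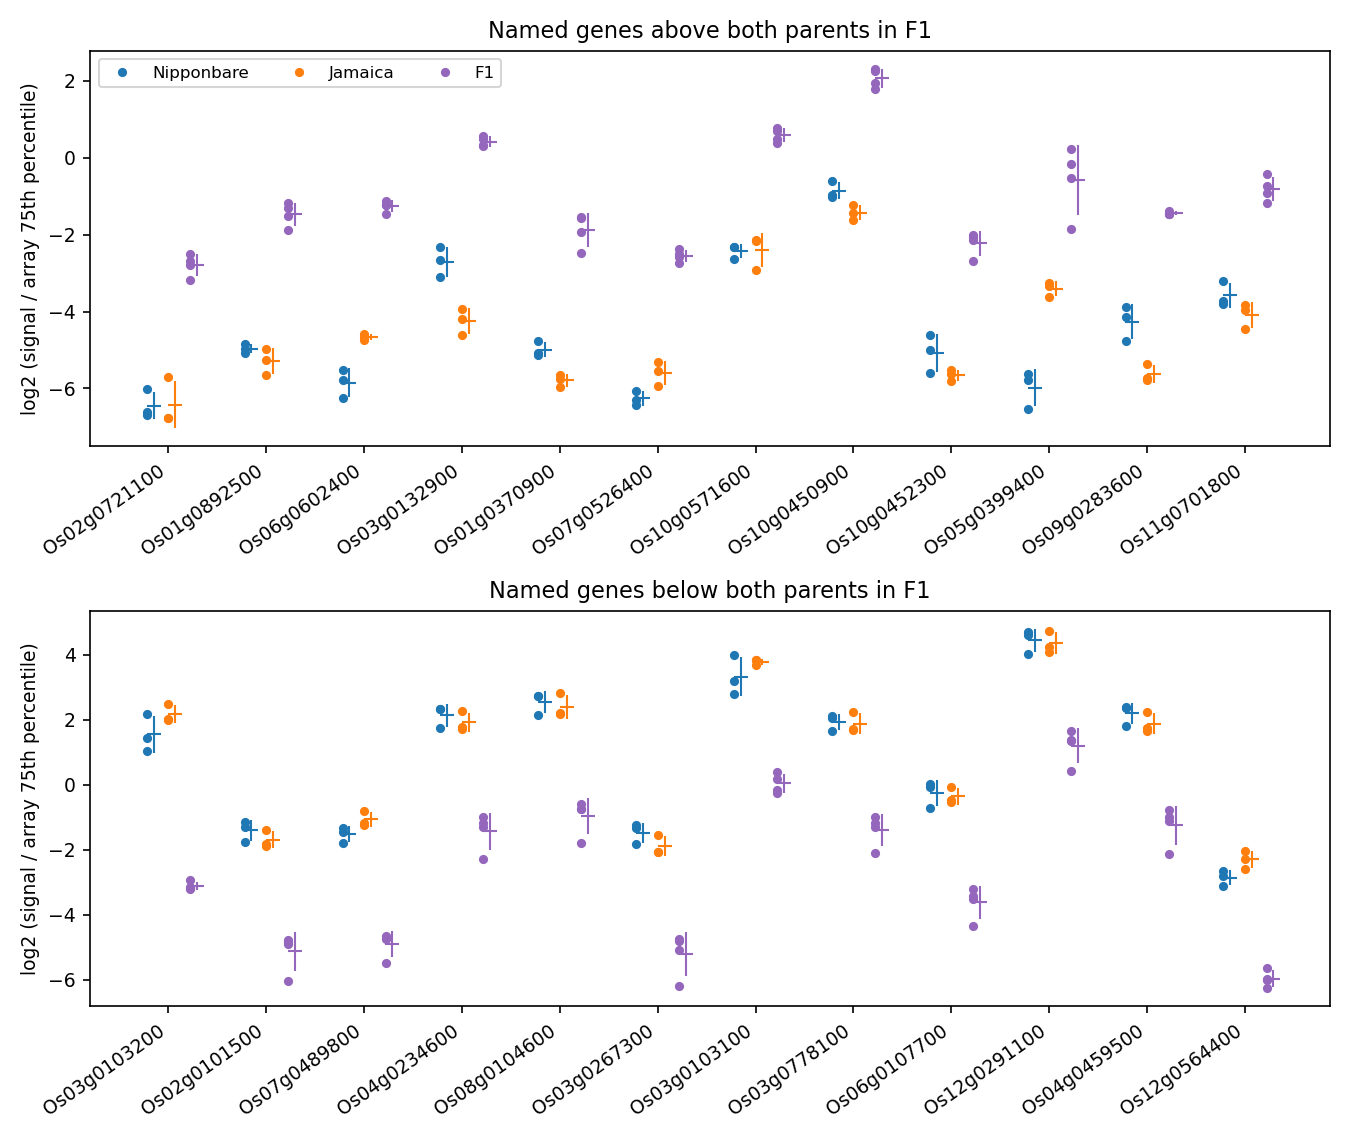
Each point is 1 array's log2 signal relative to its 75th percentile, for the 12 named genes above both parents (upper panel) and the 12 below (lower panel), in Nipponbare (3 arrays), Jamaica (3) and the F1 (4), with bars for the mean and SD. The F1 points lie clear of both parents in each gene, for example at Os05g0399400, where the F1 mean is -0.57 against -5.98 and -3.40.

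Among defence-related lists, 17 of 112 measured PR protein genes lay above both parents and 3 below (19 and 3 adjusted over the list alone), more above than among other genes (Fisher's exact test, adjusted p = 0.0389). Besides the chitinases, a beta-1,3-glucanase at Os01g0944900 was called higher, but 3 of 3 Jamaica values and 1 Nipponbare value lay at the floor, so the size of its rise is not given. The members below were a class III chitinase at Os11g0701000 (all 4 F1 values lay at the floor), a beta-1,3-glucanase-like gene at Os03g0833600 (log2 -1.08 and -0.68) and a thaumatin-family gene at Os09g0536400 (log2 -0.95 and -0.67). Against the parental mean the list was shifted up (median log2 0.32, camera adjusted p = 0.00588, and adjusted p = 0.294 with an estimated correlation), with medians of 0.30, 0.41 and 0.31 within the slides and 0.14 under normexp. Against the linear parental mean, added after seeing the data, the call was lost (median 0.14, adjusted p = 0.0668). Against single parents, also added later, the list was called up against Jamaica (median 0.38, camera adjusted p = 4.5e-05, and 0.176 with an estimated correlation). It was not called against Nipponbare (median 0.11, camera adjusted p = 0.586). Respiratory burst oxidases produce superoxide, and in their list, which includes metacaspases and vacuolar processing enzymes, 4 of 8 genes rose above both parents (5 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0239). They were all oxidases: Os12g0541300 (log2 0.79 ± 0.11 and 1.21 ± 0.11), Os01g0360200 (log2 0.76 ± 0.14 and 0.82 ± 0.14), Os05g0528000 (log2 0.85 ± 0.09 and 0.62 ± 0.09) and Os09g0438000 (log2 0.68 ± 0.10 and 0.31 ± 0.10). Another probe was not outside both parents at Os01g0360200 (log2 0.74 and 0.41, 1 of 3 others) and at Os09g0438000 (log2 0.27 and 0.18), so the count rests on the probe chosen. The call of Os09g0438000 was lost against Jamaica without F1 replicate 1, 2 or 3, Jamaica replicate 1, 2 or 3 or Nipponbare replicate 2 (adjusted p 0.0583 to 0.116) and against Jamaica with slide as a block (adjusted p = 0.0861). The list's shift from the parental mean was median log2 0.48, camera adjusted p = 0.00588 and adjusted p = 0.609 with an estimated correlation, with medians of 0.58, 0.59 and 0.44 within the slides. It was called up against Nipponbare (median 0.70, camera adjusted p = 0.00277, and 0.368 with an estimated correlation). Against Jamaica it was not called (median 0.39, camera adjusted p = 0.134). Under normexp the calls were lost against Nipponbare of Os01g0944900 (0.388) and Os12g0541300 (0.943) and against Jamaica of Os12g0541300 (0.150) and Os09g0438000 (0.106) (adjusted p in parentheses). Os12g0541300 was -0.04 against Nipponbare there.

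Glutathione S-transferases, enzymes of detoxification, went mostly the other way: 16 of 75 lay below both parents and 5 above (17 and 5 adjusted over the list alone), with more below than among other genes (Fisher's exact test, adjusted p = 0.00404). GST6 at Os09g0367700 (log2 -3.04 ± 0.16 and -2.10 ± 0.16) and Os10g0530500 (log2 -1.73 ± 0.29 and -2.65 ± 0.29) fell. Members above were Os01g0370900, Os01g0374000 (with 3 Nipponbare and 2 Jamaica values at the floor), Os01g0933900 (log2 1.22 and 1.82), Os05g0412800 (log2 1.43 and 1.04) and Os02g0319300 (log2 0.28 and 0.36). A tau class member at Os10g0529800 lay between the parents (log2 -1.79 ± 0.12 and 7.31 ± 0.12). The list was shifted down (median log2 -0.25, camera adjusted p = 0.00858, and adjusted p = 0.485 with an estimated correlation), with medians of -0.26, -0.17 and -0.28 within the slides. It was called down against Nipponbare (median -0.28, camera adjusted p = 0.00457, and 0.368 with an estimated correlation). Against Jamaica it was not called (median -0.27, camera adjusted p = 0.0942). NB-LRR receptors, the main family of plant resistance proteins, had 29 of 229 genes above both parents and 9 below (30 and 11 adjusted over the list alone), more above than among other genes (Fisher's exact test, adjusted p = 0.0389). Os11g0229500 rose above Nipponbare (log2 1.36 ± 0.23) and was at least 46.8-fold higher than in Jamaica, where no array was well above background. Os11g0222900 and Os11g0639600 lay between the parents: at least 82.2-fold and 99.6-fold higher than in Jamaica and lower than in Nipponbare (log2 -1.30 ± 0.13 and -0.53 ± 0.07). Another probe of each of these 3 loci had all 3 Jamaica values at the floor as well. Os08g0260800 was higher than in Nipponbare, where all 3 values lay at the floor, and was not called against Jamaica (log2 -0.16). The list's shift up from the parental mean (median log2 0.17, camera adjusted p = 0.00588, and adjusted p = 0.609 with an estimated correlation) had medians of 0.19, 0.10 and 0.25 within the slides and turned to -0.05 under normexp (adjusted p = 0.321), where the median of all probes was -0.06. Against the linear parental mean it was lost as well (median 0.05, adjusted p = 0.224). The list was called up against Jamaica (median 0.30, camera adjusted p = 2.7e-06, and 0.376 with an estimated correlation). It was not called against Nipponbare (median -0.07, camera adjusted p = 0.285).

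The other defence lists were not called against the parental mean. WRKY factors, a family of transcription factors, had 8 of 70 members above both parents (8 adjusted over the list alone; median log2 0.15, camera adjusted p = 0.0892) and 0 below, fewer below than among other genes (Fisher's exact test, adjusted p = 0.0408). Among them were WRKY19 at Os05g0571200 (log2 2.11 ± 0.21 and 2.09 ± 0.21), Os08g0198000 (log2 1.64 and 1.26; 1 value of each parent lay at the floor) and WRKY34 at Os01g0626400 (log2 0.61 and 1.75), of which another probe was not outside both (log2 0.25 and 0.99). Jasmonate genes had 8 of 36 above (9 adjusted over the list alone; median log2 0.23, camera adjusted p = 0.0834; Fisher's exact test, adjusted p = 0.0389). They included lipoxygenases at Os11g0575600 (log2 2.42 ± 0.24 and 2.15 ± 0.24) and Os03g0699700 (log2 2.09 ± 0.25 and 1.13 ± 0.25). In the diterpenoid phytoalexin list 2 of 10 lay above (2 adjusted over the list alone; median log2 0.84, camera adjusted p = 0.0655). They were a CYP99A1 fragment at Os04g0180400 (log2 1.80 against Nipponbare and at least 7.37-fold over Jamaica) and a terpene synthase at Os04g0179700 (with all 3 Jamaica and 2 Nipponbare values at the floor). Of 38 phenylpropanoid and lignin genes 4 lay above and 1 below (4 and 1 adjusted over the list alone; median log2 0.23, camera adjusted p = 0.0675). Those above were CAD1 at Os04g0229100 (log2 1.26 and 1.73), phenylalanine ammonia-lyase at Os04g0518400 (log2 0.44 and 1.53), a caffeoyl-CoA methyltransferase at Os09g0481400 (log2 0.80 and 0.59) and cinnamoyl-CoA reductase at Os02g0180700 (log2 0.37 and 0.89). Another caffeoyl-CoA methyltransferase at Os08g0498400 lay below (log2 -1.94 and -1.87; another probe -0.90 and -0.78). In the tryptophan and serotonin branch 1 of 17 lay above and 1 below (the same counts adjusted over the list alone; median log2 0.09, camera adjusted p = 0.645). They were an anthranilate synthase subunit at Os03g0718000 (log2 0.37 and 0.80) and an indole-3-glycerol phosphate synthase at Os04g0467700 (log2 -0.39 and -0.62). Class III peroxidases split into 16 above and 7 below of 122 (the same adjusted over the list alone; median log2 0.13, camera adjusted p = 0.426). They ran from Os02g0240100 (log2 2.38 and 2.63) to Os04g0602100 (log2 -3.56 and -4.25; 2 of 4 F1 arrays were well above background), of which another probe had all 4 F1 values at the floor. Of 3 wall-associated kinases 1 lay above, Os04g0598900 (all 3 Jamaica and 1 Nipponbare values at the floor; the same adjusted over the list alone), with a list median of 0.03 that turned to -0.20 under normexp (camera adjusted p = 0.645). Normexp ended the calls against Nipponbare of Os04g0180400 (0.744), Os04g0179700 (0.786), Os08g0198000 (0.896), Os02g0240100 (0.133) and Os04g0598900 (0.893) and against Jamaica of Os04g0180400 (0.0723), Os04g0179700 (0.206), Os08g0198000 (0.549) and Os04g0598900 (0.335) (adjusted p in parentheses). Os08g0198000 and Os04g0598900 were -0.10 and -0.10 against Nipponbare there. Leaving out 1 array brought several lists under 0.05. Diterpenoid loci were called without F1 replicate 2 (adjusted p = 0.0175) or 4 (0.0212), Jamaica replicate 1 (0.0480) or 2 (0.0351) or Nipponbare replicate 1 (0.0495). WRKY factors were called without F1 replicate 2 (0.00625), Jamaica replicate 1 (0.0174) or Nipponbare replicate 1 (0.0495). Jasmonate genes were called without F1 replicate 2 (0.0186) or Jamaica replicate 1 (0.0363), and phenylpropanoid genes without F1 replicate 4 (0.0444), Jamaica replicate 3 (0.0371) or Nipponbare replicate 3 (0.0429).

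Photosynthesis genes, used as markers of shoot tissue, formed the list that moved farthest: 60 of 110 lay below both parents and 4 above (61 and 5 adjusted over the list alone; Fisher's exact test for those below, adjusted p = 1.9e-35). A Rubisco large subunit at Os10g0356000 (log2 -4.24 ± 0.43 and -2.39 ± 0.43), small subunits at Os12g0291200 (log2 -4.02 ± 0.40 and -2.67 ± 0.40) and Os12g0291400 (log2 -3.69 ± 0.39 and -2.93 ± 0.39), and photosystem I subunit III at Os03g0778100 fell. The genes above were 3 with a plastocyanin-like domain, at Os03g0709300 (log2 1.28 and 1.36), Os06g0681200 (log2 1.23 and 3.32) and Os02g0731400 (log2 1.43 and 1.07), and Os06g0672400 of the Rubisco large chain family (log2 0.78 and 0.31). The median shift from the parental mean was -1.71 (camera adjusted p = 2.2e-12, and adjusted p = 0.294 with an estimated correlation), with -1.70, -1.70 and -1.54 within the slides and -1.31 under normexp. It was the one list called in the same direction against Nipponbare (adjusted p = 3.3e-08) and against Jamaica (adjusted p = 3.0e-11), a comparison added after seeing the data. With an estimated correlation both of these calls were lost (adjusted p = 0.368 and 0.358).

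Markers of other tissues and cell types were not called. Seed proteins (median log2 0.06, camera adjusted p = 0.695) had 5 of 34 above and 2 below (the same adjusted over the list alone), and their median turned to -0.06 under normexp. Those above were late embryogenesis genes at Os01g0314800 (log2 1.57 and 1.04), Os05g0542500 (log2 0.89 and 1.03), Os05g0584200 (log2 0.52 and 0.47) and Os01g0624400 (log2 0.47 and 0.45) and an immunoglobulin-like gene at Os01g0100500 (log2 0.16 and 0.18) that the name pattern for globulins took in. Glutelins at Os01g0762500 (log2 -1.17 and -2.02) and Os10g0400200 (log2 -0.38 and -0.41) lay below, though another probe of the latter was not outside both (log2 -0.16 and -0.34). Vessel and sclerenchyma markers (median log2 -0.07, camera adjusted p = 0.820) had 2 of 23 above, a COBRA protein at Os07g0604300 (log2 1.89 and 0.76) and a laccase at Os01g0827300 (log2 0.85 and 0.62). Below were 3, the laccases Os01g0842500 (log2 -1.41 and -1.85), Os05g0458300 (log2 -0.97 and -1.01) and Os12g0257800 (log2 -0.78 and -0.89), with the same counts adjusted over the list alone. Their medians within the slides were 0.21, 0.64 and -0.80. The call of Os01g0842500 was lost against Nipponbare without F1 replicate 1, 3 or 4, Jamaica replicate 1 or Nipponbare replicate 2 or 3 (adjusted p 0.0540 to 0.127) and against Nipponbare with slide as a block (adjusted p = 0.0570). Endodermis and exodermis markers (median log2 -0.18, camera adjusted p = 0.695; mean 0.24) had 1 of 4 below, a dirigent-like gene at Os07g0638500 (log2 -0.77 and -1.94). It was not called when adjusted over the list alone or against Nipponbare without F1 replicate 1 or 4, Jamaica replicate 1 or 3 or Nipponbare replicate 2 or 3 (adjusted p 0.0502 to 0.113). Root cap and meristem markers (median log2 -0.02, camera adjusted p = 0.891; mean 0.00) had 1 of 16 above, Os04g0410400 (log2 1.54 and 1.60). Below was 1, Os01g0968200 (log2 -1.46 against Jamaica), which was not called when adjusted over the list alone. The call of Os01g0968200 was lost against Nipponbare without F1 replicate 3 or 4 or Nipponbare replicate 2 or 3 (adjusted p 0.0516 to 0.0770) and against Nipponbare with slide as a block (adjusted p = 0.0545). It was also lost against Jamaica without F1 replicate 3 or 4 or Jamaica replicate 1 or 3 (adjusted p 0.0789 to 0.113) and against Jamaica with slide as a block (adjusted p = 0.0671). The list's median was 0.03 with the deposited values. Root hair markers (median log2 0.14, camera adjusted p = 0.774; 3 genes) included Os01g0575000 (log2 0.13 and 0.15), which differed from neither parent. Normexp ended the calls against Nipponbare of Os07g0604300 (0.0532) and against Jamaica of Os07g0604300 (0.235) and Os12g0257800 (0.0523) (adjusted p in parentheses).

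**Figure D2:**
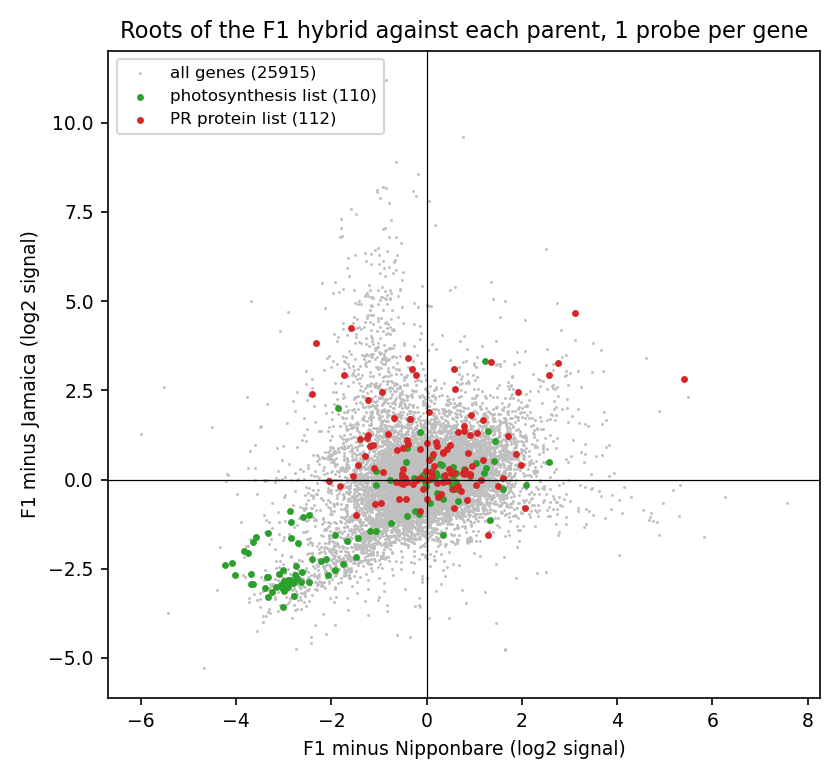
Each point is 1 gene (25915 genes, 1 probe each), with F1 minus Nipponbare on the horizontal axis and F1 minus Jamaica on the vertical axis, both as log2 signal. Photosynthesis genes (green, 110) gather in the lower left, with a median of -1.72 and -1.45, whereas PR protein genes (red, 112) reach higher values with medians of 0.11 and 0.38.

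Among growth-related lists, 15 of 94 cell wall expansion and cellulose genes lay above both parents and 3 below (15 and 4 adjusted over the list alone), more above than among other genes (Fisher's exact test, adjusted p = 0.0389). The list's shift was not called (median log2 0.24, camera adjusted p = 0.0892; 0.30, 0.80 and -0.07 within the slides). Among those above were expansins, which loosen cell walls: a beta-expansin at Os10g0555900 (log2 2.00 and 1.76) and EXPA13 at Os02g0267200 (log2 1.52 and 1.42). The genes below were a cellulose synthase family gene at Os07g0551500 (log2 -1.91 and -2.00), a beta-expansin at Os03g0102700 (log2 -1.04 and -1.04) and Os03g0377700 (log2 -0.49 and -0.47), a cellulose synthase-like gene. Without F1 replicate 4 or Nipponbare replicate 3 this list was called (adjusted p = 0.0247 and 0.0259). Histones were shifted up from the parental mean (median log2 0.31, camera adjusted p = 0.0143, and adjusted p = 0.895 with an estimated correlation), with 6 of 44 genes higher, and medians of 0.29, 0.77 and -0.01 within the slides. Without F1 replicate 2 that call was lost (median 0.21, adjusted p = 0.105), as it was over all probes (adjusted p = 0.0669). Of the 44 histone genes 0 lay above and 0 below both parents. The list's median was 0.48 against Nipponbare (camera adjusted p = 0.0163, and 0.878 with an estimated correlation) and 0.03 against Jamaica (camera adjusted p = 0.387). The histone H2B genes Os01g0152700 (log2 -0.64 ± 0.12 and 8.91 ± 0.12) and Os01g0152300 (log2 -0.41 ± 0.12 and 2.00 ± 0.12) stood well above Jamaica. Of 36 cell cycle and replication genes (median log2 0.18, camera adjusted p = 0.350), 1 lay above, a cyclin-dependent kinase inhibitor at Os09g0459900 (log2 1.18 and 0.50). Below were 2, cell division protein kinase 4 at Os05g0480000 (log2 -1.94 and -2.21) and a replication factor C subunit at Os12g0176500 (log2 -0.21 and -0.37), with the same counts adjusted over the list alone.

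Ribosomal proteins had 0 of 247 genes above both parents, fewer than among other genes (Fisher's exact test, adjusted p = 3.1e-07), and 14 below (12 adjusted over the list alone; adjusted p = 0.521). The genes of this list had an estimated correlation of 0.615, which that test leaves out. Those farthest below were L17 at Os03g0815400 (log2 -2.65 ± 0.11 and -3.17 ± 0.11), a 9S protein at Os03g0769100 (log2 -1.74 ± 0.09 and -2.70 ± 0.09), L6 at Os03g0356300 (log2 -1.71 and -2.61) and L10-like at Os03g0284400 (log2 -1.83 and -2.25). The list's median lay near 0 (median log2 -0.01, camera adjusted p = 0.168; 0.01, 0.37 and -0.27 within the slides) and was 0.02 under normexp and 0.03 with the deposited values. It was called lower without F1 replicate 2 (adjusted p = 4.9e-05) or Nipponbare replicate 1 (0.0315). Heat shock proteins and chaperones had 9 of 161 above and 17 below (8 and 16 adjusted over the list alone; median log2 0.03, camera adjusted p = 0.667; mean -0.03 and test direction down). A DnaJ-domain gene at Os11g0216100 (log2 -2.00 ± 0.20 and -2.04 ± 0.20) and the Rubisco-binding chaperonin subunit at Os12g0277500 (log2 -1.48 ± 0.08 and -2.17 ± 0.08), which the photosynthesis list shares, fell. Auxin genes had 7 of 79 above and 7 below (the same adjusted over the list alone). They included GH3 at Os07g0592600 (log2 1.80 and 1.28) and AUX/IAA at Os02g0805100 (log2 -1.65 and -1.54). The list median of 0.04 turned to -0.10 under normexp (camera adjusted p = 0.891). Another GH3 gene at Os07g0576500 was at least 12.3-fold higher than in Nipponbare, where no array was well above background. In the ethylene list 9 of 75 lay above and 5 below (the same adjusted over the list alone), with a median of 0.09 that was -0.01 under normexp (camera adjusted p = 0.645). ACC oxidase, which makes ethylene, rose at Os09g0451000 (log2 1.78 ± 0.20 and 2.62 ± 0.20). A translation release factor at Os05g0373900 (log2 1.10 and 0.85) and a small GTP-binding protein at Os07g0239400 (log2 0.39 and 0.48) were taken in by the name pattern. Those below were ACC synthase family genes at Os10g0484700 (log2 -0.73 and -0.48) and Os06g0130400 (log2 -0.68 and -0.24). Also below were ethylene-responsive factors at Os02g0655200 (log2 -0.63 and -0.67), Os05g0316800 (log2 -0.69 and -0.52) and Os01g0131600 (log2 -0.26 and -0.69). Of the 5 other probes of the last, 2 were not outside both (log2 0.06 and -1.10, and -0.21 and -0.68).

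Lists of transport and metabolism were not called. Aquaporins, water channels, had 3 of 13 above (median log2 0.41, camera adjusted p = 0.0892; the same adjusted over the list alone). They were Os07g0448200 (log2 1.58 ± 0.16 and 1.99 ± 0.16), Os02g0823100 (log2 0.66 and 0.93) and Os04g0521100 (log2 0.91 and 0.48). The last lost its call against Jamaica without F1 replicate 1, 3 or 4 or Jamaica replicate 1 or 3 (adjusted p 0.0515 to 0.0998). Nitrogen genes (median log2 0.10, camera adjusted p = 0.426) had 5 of 34 above and 3 below (the same adjusted over the list alone). Above were glutamine synthetases at Os03g0712800 (with 2 of 3 Nipponbare values at the floor; another probe, with all 3 Nipponbare values at the floor, was not outside both), Os02g0735200 (log2 1.44 and 0.92) and Os03g0223400 (log2 1.24 and 0.58). Ammonium transporter genes above were Os02g0620600 (log2 1.68 and 1.42) and Os03g0838400 (log2 0.57 and 1.09). Below were the chloroplast glutamine synthetase at Os04g0659100 (log2 -0.64 and -0.59), of which another probe lay above both (log2 0.27 and 0.65), and nitrate reductases at Os08g0468700 (log2 -0.46 and -1.26) and Os08g0468100 (log2 -0.40 and -1.23). Iron uptake genes (median log2 -0.01, camera adjusted p = 0.645; 0.01 with the deposited values) split. A gene that the array files name IRT1, an iron transporter, fell at Os03g0667300 (log2 -2.79 ± 0.31 and -2.34 ± 0.31; 3 of 4 F1 arrays were well above background). So did a gene they name Nramp6, at Os07g0258400 (log2 -1.45 and -1.38). These names were not checked against current ones. Another iron-regulated transporter at Os03g0667500 (log2 1.77 and 0.99) and a nicotianamine synthase at Os07g0689600 (log2 0.54 against Nipponbare) rose. These were 2 of 14 above and 2 below, the same adjusted over the list alone. Calls were lost at Os03g0667500 against Jamaica without Jamaica replicate 1, 2 or 3 (adjusted p 0.0522 to 0.0593) and at Os07g0689600 against Nipponbare without Nipponbare replicate 1 or 2 (adjusted p 0.0659 to 0.0779). In the phosphate list (median log2 0.06, camera adjusted p = 0.774; -0.03 under normexp) 2 of 32 rose, SPX-domain genes at Os02g0202200 (log2 0.61 and 1.46) and Os03g0650900 (log2 0.23 and 0.80). Those that fell were 2, a phosphate transporter at Os02g0593500 (log2 -3.16 ± 0.25 and -2.49 ± 0.25) and an SPX-domain gene at Os02g0678200 (log2 -0.94 and -1.11), the same adjusted over the list alone. Os02g0202200 lost its call against Nipponbare without Nipponbare replicate 2 or 3 (adjusted p 0.0582 to 0.0961). Sugar genes (median log2 0.06, camera adjusted p = 0.426) had 9 of 49 above (Fisher's exact test, adjusted p = 0.0514) and 3 below (the same adjusted over the list alone). A trehalose-6-phosphate phosphatase at Os07g0624600 (log2 2.34 ± 0.27 and 2.81 ± 0.27) and a sucrose synthase at Os04g0309600 (log2 2.53 and 0.84) rose. An ADP-glucose synthesis enzyme at Os08g0345800 (log2 -1.91 and -1.23), a beta-amylase at Os10g0465700 (log2 -0.97 and -0.75) and a neutral invertase at Os02g0529400 (log2 -0.21 and -0.26) fell, with another probe of the last not outside both (-0.21 and -0.25). Os04g0309600 lost its call against Jamaica without Jamaica replicate 3 (adjusted p = 0.0704). Anaerobic genes (median log2 -0.11, camera adjusted p = 0.787; 16 genes) had 4 higher and 3 lower than the parental mean. Normexp ended the calls against Nipponbare of Os03g0712800 (0.648), Os03g0667500 (0.0542) and Os04g0309600 (0.0848) and against Jamaica of Os03g0712800 (0.563), Os03g0667500 (0.134) and Os04g0309600 (0.288) (adjusted p in parentheses).

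Of the 30 lists, 6 were called against the parental mean by camera at the preset correlation (4 up, 2 down). With an estimated correlation 0 were, where 3 had an unadjusted p under 0.05, against 12 at the preset correlation and 18 with fry. After adjustment fry called 16.

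**Figure D3:**
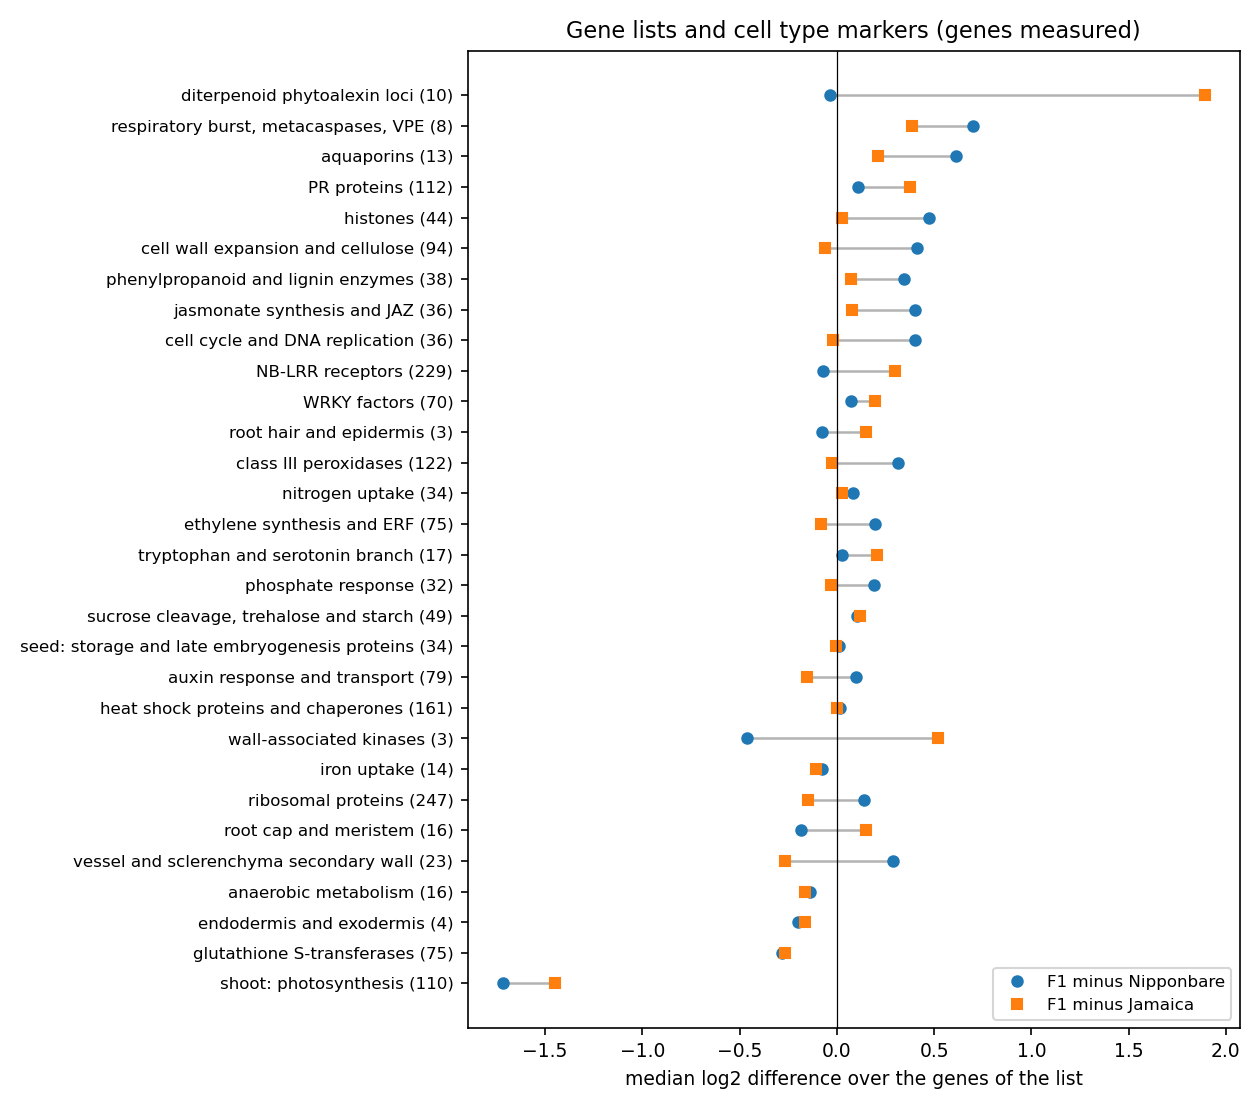
The horizontal axis gives the median log2 difference of the F1 from Nipponbare (circles) and from Jamaica (squares) over the genes of each list, with the number of genes in parentheses, ordered by the shift from the parental mean. Photosynthesis markers lie at -1.72 and -1.45 at the bottom, and the signs of several medians near 0 (NB-LRR receptors, wall-associated kinases, auxin, ethylene, phosphate and seed lists, ribosomal proteins, iron uptake and root cap markers, against the parental mean) turn with the scaling.

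Compared with single parents, the F1 differed from Nipponbare at 16036 of 37299 probes (43.0%; 7902 higher, 8134 lower; 5208 at 2-fold or more) and from Jamaica at 13453 (36.1%; 7392 higher, 6061 lower; 4848 at 2-fold or more). Genes with a large difference between the parents took part in both. Histone H2B at Os01g0152700 stood at log2 3.09 ± 0.07 (SD, n = 3) in Nipponbare, 2.44 ± 0.07 (n = 4) in the F1 and -6.46 ± 0.27 (n = 3) in Jamaica. Os08g0498600, a caffeoyl-CoA methyltransferase fragment, was higher in the F1 than in Nipponbare and lower than in Jamaica (log2 3.88 ± 0.15 and -0.83 ± 0.15). An extensin-like gene at Os12g0542200 was at least 31.1-fold higher in the F1 than in Nipponbare, where no array was well above background. An ERF-domain gene at Os10g0562900 was at least 29.4-fold higher than in Jamaica. Against the mean of the parents' log2 values, 13293 probes differed (7180 higher, 6113 lower; 3592 at 2-fold or more). With slide as a block the counts were 14901, 12763 and 12185. Under normexp they were 9055, 7564 and 6854, with 37.1%, 57.3% and 48.3% higher against 49.3%, 54.9% and 54.0%.

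The normal parents also differed from each other. Genes much higher in Jamaica were a response regulator at Os06g0647200 (log2 6.76 ± 0.20 against Nipponbare), acid phosphatases at Os05g0191700 (log2 6.42 ± 0.26) and Os05g0192100 (log2 5.90 ± 0.18), and S-adenosylmethionine synthetase at Os01g0293000 (log2 5.46 ± 0.12). They also included chalcone synthase C2 at Os11g0530600 (log2 5.46 ± 0.41). A BURP-domain gene at Os05g0215000 (log2 4.92 ± 0.40), the caffeoyl-CoA methyltransferase at Os08g0498600 (log2 4.71 ± 0.17) and GOS9 at Os03g0399900 (log2 4.65 ± 0.18) followed. Much lower in Jamaica were histone H2B at Os01g0152700 (log2 -9.55 ± 0.12), the tau class glutathione S-transferase at Os10g0529800 (log2 -9.11 ± 0.13), a gene named surface protein PspC at Os07g0599700 (log2 -8.39 ± 0.17) and a Clp protease subunit at Os12g0230100 (log2 -7.34 ± 0.12). A germin at Os08g0231400 (log2 -6.77 ± 0.15), MADS56 at Os10g0536100 (log2 -6.48 ± 0.22), an Xaa-Pro aminopeptidase at Os11g0540100 (log2 -6.26 ± 0.10) and a phytoene dehydrogenase-like gene at Os12g0631800 (log2 -5.99 ± 0.24) were lower as well. For all 16 genes every Jamaica array lay beyond every Nipponbare array (n = 3 and 3), with limma adjusted p-values of 4.1e-11 to 1.4e-05. Other probes of the same locus gave log2 1.01 to 5.05 at Os05g0215000, and at Os11g0530600 another probe had all 3 Nipponbare values at the floor. At Os12g0631800, 1 of 3 Jamaica values lay at the floor. Of 37299 probes 16390 differed (43.9%; 8315 higher and 8075 lower in Jamaica; 5471 at 2-fold or more), 15501 with slide as a block. Normexp, which moved the median of all probes from 0.03 to -0.18, called 8849, with 35.3% of them higher against 50.7%.

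Among the lists, NB-LRR receptors were lower in Jamaica, with 33 of 229 genes higher and 113 lower in Jamaica (36 and 118 adjusted over the list alone) (median log2 -0.39, camera adjusted p = 4.8e-06, and adjusted p = 0.441 with an estimated correlation; -0.44, -0.29 and -0.36 within the slides). Os11g0222900 and Os11g0639600 were at least 202-fold and 144-fold lower there, where another probe of each also lay at the floor on all 3 Jamaica arrays. PR proteins were lower too, with 22 of 112 genes higher and 47 lower in Jamaica (24 and 49 adjusted over the list alone) (median log2 -0.42, camera adjusted p = 0.00551, and adjusted p = 0.441 with an estimated correlation; -0.53, -0.23 and -0.44 within the slides). Diterpenoid phytoalexin loci were lower with 7 of 10 genes lower in Jamaica (8 adjusted over the list alone; median log2 -1.86, camera adjusted p = 0.00376, and adjusted p = 0.441 with an estimated correlation; -1.58, -1.57 and -2.29 within the slides). Among them was Os02g0570700, a P450 gene at least 4.25-fold lower. Ribosomal proteins were higher in Jamaica, with 46 of 247 genes higher and 9 lower in Jamaica (13 and 9 adjusted over the list alone) (median log2 0.31, camera adjusted p = 4.4e-05, and adjusted p = 0.719 with an estimated correlation; 0.46, 0.30 and 0.16 within the slides; fry adjusted p = 0.0926). Cell cycle genes were higher (median log2 0.51, camera adjusted p = 0.00376, and adjusted p = 0.676 with an estimated correlation; 0.61, 0.58 and 0.31 within the slides), with 18 of 36 genes higher and 2 lower in Jamaica (19 and 3 adjusted over the list alone). Among those higher was a dihydrofolate reductase-thymidylate synthase at Os12g0446900 (log2 2.03 ± 0.17). Cell wall genes were higher, with 35 of 94 genes higher and 6 lower in Jamaica (39 and 6 adjusted over the list alone) (median log2 0.57, camera adjusted p = 0.00536, and adjusted p = 0.719 with an estimated correlation; 0.88, 0.47 and 0.35 within the slides; fry adjusted p = 0.103). Auxin genes were higher, with 29 of 79 genes higher and 8 lower in Jamaica (29 and 8 adjusted over the list alone) (median log2 0.34, camera adjusted p = 0.00696, and adjusted p = 0.441 with an estimated correlation; 0.37, 0.35 and 0.30 within the slides). The GH3 gene at Os07g0576500 was at least 15.3-fold higher in Jamaica. Vessel markers were not called (median 0.80, adjusted p = 0.152), but were without Jamaica replicate 2 (0.0460) or Nipponbare replicate 3 (0.0231). Without the latter array, called lists were also phenylpropanoid genes (0.19 and 0.117 over all arrays, 0.0480 without it) and histones (0.48 and 0.261 over all arrays, 0.0192 without it). Of the 30 lists, 7 were called (4 up, 3 down). With an estimated correlation 0 were, where 3 had an unadjusted p under 0.05, against 9 at the preset correlation and 18 with fry, which called 17 after adjustment.

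The lists not called between the parents had these medians and camera adjusted p-values: photosynthesis 0.01 (0.901), tryptophan -0.07 (0.316), WRKY factors -0.05 (0.349), peroxidases 0.43 (0.212), glutathione S-transferases -0.15 (0.253), wall-associated kinases -0.99 (0.212) and respiratory burst 0.30 (0.333). The others were heat shock 0.01 (0.941), jasmonate 0.24 (0.212), ethylene 0.26 (0.316), aquaporins 0.28 (0.378), nitrogen 0.28 (0.299), phosphate 0.20 (0.360), iron 0.06, sugars -0.03 (0.656), anaerobic 0.32 (0.476), seed 0.03 (0.868), endodermis -0.03 (0.693), root hair -0.18 (0.525) and root cap -0.09 (0.339). Median, mean and test differed in sign for heat shock (mean 0.01, test down), iron (mean -0.02, test down) and photosynthesis (mean -0.10, test up). Medians changed sign under normexp for photosynthesis, heat shock, ethylene, phosphate, seed and endodermis, with the deposited values for photosynthesis, heat shock and seed, and with quantile normalization for WRKY factors.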

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

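No test in this part was chosen after its result was seen. Each of 181 sets of 4 F1 values (named genes and list means per array) was searched for an array far from the others, by its gap to the nearest divided by the whole range, against Dixon's 95% limit. Chance alone passes this limit in about 1 of 20 sets, or 9.05 of 181. It was passed in 19, and the far array was F1 replicate 2 in 18 of them. In brackets stand the ratio, the far log2 value and the values of the other 3 arrays. Among list means replicate 2 was far in heat shock proteins (0.915), auxin (0.871; -1.70 against -1.86 to -1.84), cell cycle (0.873; -1.97 against -2.19 to -2.16), histones (0.899; 1.89 against 1.44 to 1.49), ribosomal proteins (0.869; 2.12 against 1.69 to 1.74) and nitrogen genes (0.951; -0.39 against -0.38). Photosynthesis and photorespiration genes were lower on it: Os02g0101500 (0.905; -6.03 against -4.90 to -4.78), Os07g0489800 (0.875; -5.49 against -4.75 to -4.65), Os08g0104600 (0.856; -1.78 against -0.76 to -0.58) and Os12g0291400 (0.929; -3.04 against -1.60 to -1.49). So were Os06g0647200 (0.835; -0.16 against 0.23 to 0.31), Os11g0216100 (0.916; -3.11 against -2.56 to -2.51), Os02g0593500 (0.832; -6.26 against -5.48 to -5.32) and Os12g0151000 (0.863; -4.37 against -4.02 to -3.97). Higher on it were Os04g0510900 (0.901; -4.04 against -4.97 to -4.87), Os01g0293000 (0.877; 1.12 against 0.76 to 0.81), Os03g0667500 (0.916; -1.17 against -2.39 to -2.29) and Os02g0697400 (1; -6.56 against -6.78), where the other 3 arrays lay at the floor. Replicate 3 was far in Os07g0448200 (0.906; 2.14 against 2.59 to 2.64). Without replicate 2, 5796 probes lay outside both parents and 9 lists were called against the parental mean. The cause was not tested.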

How the results depend on the processing

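The counts of calls kept within 1.5 times of the main setting under quantile normalization, no filter on dim probes, a filter asking for all 10 arrays, the deposited table and slide as a block, as did the 3 pairwise probe counts with only the groups compared and the 5 probe counts with eBayes trend and robust. Normexp called 9055 (F1 against Nipponbare), 7564 (F1 against Jamaica), 8849 (Jamaica against Nipponbare), 3092 (outside both parents) and 6854 (against the parental mean), with 37.1%, 57.3%, 35.3%, 32.7% and 48.3% higher against 49.3%, 54.9%, 50.7%, 45.5% and 54.0%, and 12 lists between the parents; the cause was not tested. A further 2-fold threshold left 5208, 4848, 5471, 1957 and 3592 by its construction, with 41.6%, 48.0%, 42.6%, 26.0% and 42.8% higher. An estimated correlation left 0 and 0 lists (F1 against the parental mean, Jamaica against Nipponbare), with 3 and 3 at an unadjusted p under 0.05 against 12 and 9 with the preset one and 18 and 18 with fry. All probes of a gene gave 11 and 13 lists and fry 16 and 17, and 1 list was called the same way against each parent, an alternative added after seeing the data; the cause was not tested. Leaving out 1 array gave 11670 to 16736, 10837 to 14502, 11997 to 18117, 4741 to 5796 and 11034 to 14253 probes and 6 to 9 and 7 to 10 lists. With the replicate number as a block the counts were 15682, 12170, 15956, 5489 and 12540 probes and 9 and 7 lists. Between the parents, where the rule for pairing was met by number, the block changed no call of the 16 named genes and 30 lists. Same-numbered F1 and parental arrays, which also share a slide, are not paired by that rule (lowest r -0.04), and not every array correlated best with its own number. Added after seeing the data, the linear parental mean gave 12691 probes and 4 lists, and F1 arrays in 2 sets of 2 gave 4167 to 4644 probes outside both. Over 8189 checks of 435 values of named genes, 7787 were the same, 339 weaker, 36 stronger and 6 reversed, 21 uncalled values changed sign, and 252 of 397 calls kept everywhere. The reversed values, all F1 minus Nipponbare under normexp, were -0.10 at Os08g0198000, -0.00476 at Os03g0758900, -0.10 at Os04g0598900, -0.0355 at Os12g0541300, -0.0473 at Os06g0604000 and -0.25 at Os09g0541000; the cause was not tested. Over 1230 checks of 60 list values, 1100 were the same, 20 weaker, 69 stronger and 0 reversed, 41 uncalled values changed sign, and 0 of 13 calls kept everywhere. Signal over background limits the dim genes, for which only bounds are given.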

Other observations

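The tests of product names and chromosomes, the linear parental mean, the calls against each parent, the F1 arrays in 2 sets of 2, the loci with 1 probe, the shoot identity genes with room to fall and the splits for single lists other than photosynthesis were chosen only after results had been seen. Product names shared by at least 8 genes (229 names, 458 one-sided Fisher's exact tests, adjusted together) were compared with the remaining genes, leaving genes of the 30 lists out of the names. Below both parents were 9 of 16 rhodanese-like genes (adjusted p = 3.6e-04), such as Os02g0257300 (log2 -2.78 and -3.07) and Os01g0896500 (log2 -2.91 and -2.49). So were 6 of 8 PAP fibrillin genes (0.00132), which code for plastid lipid-associated proteins, such as Os04g0607000 (log2 -1.32 and -1.90). This count rests on the probe chosen. Another probe was not outside both at Os04g0422000 (log2 -0.18 and -0.60, with 2 F1 values at the floor). The same held at Os11g0595200 (log2 -1.64 and 0.57, with all 3 Jamaica values at the floor). Of genes with the product name DEAD/DEAH box helicase, N-terminal, 7 of 13 lay below (0.00318), with Os02g0739000 (log2 -1.85 and -2.49) and Os11g0533100 (log2 -1.49 and -1.93). Helicases with other names were not counted there, such as Os06g0602400, which rose (log2 4.60 and 3.41). Of the TPR-like genes 44 of 309 lay below (0.00900), with Os10g0181200 (log2 -2.65 and -3.39), and of the protein prenyltransferase genes 21 of 124 (0.0399), with Os05g0586900 (log2 -1.91 and -2.35). Above both parents were 5 of 8 receptor kinase-like genes (0.00900): Os11g0569500 (log2 1.34 and 0.83), Os08g0374600 (log2 0.76 and 2.05), Os11g0570000 (log2 0.66 and 1.07), Os11g0569800 (log2 0.76 and 0.42) and Os02g0215900 (log2 0.28 and 0.98), though another probe of Os08g0374600 was not outside both (log2 0.39 and 0.45). So were 62 of 526 protein kinase genes (0.0117), with Os08g0203400 (log2 2.53 and 2.53), 11 of 49 plant-specific leucine-rich repeat genes (0.0399), with Os02g0277700 (log2 1.28 and 1.92), and 6 of 17 curculin-like lectin genes (0.0482), with Os03g0828800 (log2 1.71 and 2.61) and Os01g0958200 (log2 1.17 and 1.76).

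Genes at least 8-fold apart between the parents were most frequent on chromosome 11 (4.82% of genes, Fisher's exact test against the other chromosomes, adjusted p = 2.9e-07), 10 (4.05%, 8.2e-04), 12 (0.0264) and 8 (3.33%, 0.0264), and least on 3 (1.23%, 2.2e-06), 2 (1.56%, 0.00220) and 1 (1.79%, 0.0133). The share of genes outside both parents was not called different on any chromosome (lowest adjusted p = 0.455).

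Photosynthesis genes were lower in the F1 roots than in both parents. Array scaling was argued against, since the list median stayed at -1.67 with the deposited values, -1.68 with quantile normalization and -1.31 with normexp. Less shoot tissue in the F1 samples was weighed by a bound written beforehand, -0.86, which is 0.5 of the photosynthesis median. Shoot identity genes had a median of -0.0139 (bootstrap 95% interval -0.28 to 0.13, over 9 measured genes), above that bound. Of the 9, 7 had room to fall by that much above the floor, with a median of 0.03 and the lowest at -0.35. The test takes these genes as specific to shoots, which no array here measured. Os06g0646600 was high in all these roots (2.94 in the F1, 3.06 in Jamaica and 3.37 in Nipponbare). So was Os01g0575500 (0.89, 0.83 and 0.90), named stomatal cytokinesis defective, whose value is the median of the 7. It is named neither YABBY nor knotted1-type homeobox, the gene classes that the bound was written for. The gene at the median of all 9, Os03g0673000, lay near the floor (-6.72 in the F1 and -6.68 in Nipponbare). Such genes could hide a lost share of shoot tissue, so the test cannot decide this question. Less shoot tissue stays open, as does a change of plastid genes within F1 roots, which was not tested.

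NB-LRR receptors had a higher median than the parental mean in the F1 and a lower one in Jamaica. Averaging the parents on the log scale could account for the shift: against the linear mean the median was 0.0522 (adjusted p = 0.224) against 0.17. In a simulation an additive list with a drop of log2 3 in Jamaica gave 0.66 against the log mean and -0.01 against the linear one. The 29 genes above both parents do not rest on that mean and stay open.

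At 697 probes (565 loci) the signal was at least 8-fold lower in Jamaica than in Nipponbare. A differing site confined to 1 probe was argued against for loci with another probe. At 164 loci the other probes had a median of -3.19 (95% interval -3.40 to -2.81) against -4.33, and 20 (12.2%) lay within 2-fold. Probe sequences were not compared, so probes of a locus can cover the same site, and a difference at a shared site stays open. For 401 loci with 1 probe a differing site cannot be told apart from lower expression, for want of another probe. A gene missing or diverged as a whole in Jamaica stays open, since no genome was used here. The mirror set, at least 8-fold higher in Jamaica, had 171 probes, with 3.33 at other probes of 29 loci.

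Chance was weighed by splitting the arrays into groups of the same sizes, in all ways between 2 groups and in 99 random ways beside the real one over all 3 groups. For F1 against Nipponbare 1 of 35 splits, the real one, reached the count (highest other 348), and for F1 against Jamaica 1 of 35 (4688). For probes outside both it was 1 of 100 (1), for the parental mean 1 of 100 (5147), and for the photosynthesis median 1 of 100 (farthest other 1.29). These shares lie under 0.05 and, as the real split is counted, are the smallest possible. They were not adjusted over the results tested, so chance is made less likely there but not excluded. The other splits over all 3 groups mix arrays of groups that differ, which widens the spread within a group. For probes outside both they weigh only whether any groups differ. They cannot tell an F1 outside both parents from an F1 between them. Between the parents 1 of 10 splits reached the probe count (highest other 0) and 5 of 10 the list count (highest other 12), too few splits for a share under 0.05. Of these 10, 4 part all 3 same-number pairs: the real one and 3 that called 0 probes and 5, 5 and 11 lists. The 6 others part 1 pair and called 0 probes and 1 to 12 lists. For lists against the parental mean 70 of 100 splits reached 6 (highest other 13), so chance was not excluded. For the lists called, the number of the 100 splits with a median as far from 0 and with a camera p as small was 1 and 2 for photosynthesis, 2 and 22 for PR proteins, 1 and 10 for glutathione S-transferases, 2 and 10 for the respiratory burst list, 13 and 35 for NB-LRR receptors and 22 and 37 for histones. A share under 0.05 was thus not reached for NB-LRR receptors and histones by either measure, nor by the camera p for PR proteins, glutathione S-transferases and the respiratory burst list.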
